A study of Caenorhabditis elegans with 4 samples.

How the data were processed

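Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on adult Caenorhabditis elegans of the strain fem-2(b245), which carries a mutation in a phosphatase gene of the sex determination pathway. The series holds 4 samples, namely 2 ChIP samples and 2 input samples (sheared genomic DNA that was not immunoprecipitated). The labels' protocols describe animals frozen, ground in a mixer mill, fixed in 1% formaldehyde for 10 minutes and sonicated, with 5 µg of affinity-purified antibody per ChIP. The series' design text gives a temperature of 20 degrees Celsius. The labels describe the animals as young adults with a germline, whereas the growth protocol describes harvest of gravid adults. The sample titles name KLE-2, a subunit of condensin II, with the antibody code SDQ3898. The antibody descriptions of the same samples instead name CEC-1, a chromodomain protein, with the code SDQ2901. The lists themselves do not settle which of these targets was immunoprecipitated, so the samples are called ChIP replicate 1 and ChIP replicate 2 throughout. The labels do not say whether the replicates came from separate cultures.

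The analysed files were 3 peak lists, with coordinates on WormBase WS220 per the file headers, a build called ce10 in the submitters' processing notes. Reads were aligned with BWA, per the submitters' processing notes, which give no version. Each replicate list names MACS without a version as its caller, per the file contents, and was deposited with its own ChIP sample. The third list was deposited for the whole series, names MACS v2, and numbers its peaks under the series title. Whether it was called on pooled replicates, on which input, with which threshold and how duplicate or multiply aligned reads were treated is not given in the sources used here. Every peak in the deposited lists has a position and a score from the authors' peak caller, and the scale of the score is not stated. In the replicate lists the lowest scores lay just above 50. Many peaks had a score of exactly 3100 (45 in replicate 1 and 1011 in replicate 2), and a few scored above it. Peaks at or above that value cannot be ranked by strength, since a score above 3100 need not mean a stronger peak than one of 3100. In the whole-series list scores ran from 1.31 to 246.9. Scores were therefore compared only within a list or by rank, never in size between the whole-series list and the replicates. Read counts, signal tracks and values of the input samples were not used here, so the depth behind each peak is unknown, and ChIP could not be set against input.

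Chromosome lengths of WS220 were entered as a setting. The highest peak end reached from 99.9% to 100% of these lengths on each nuclear chromosome, and 1 whole-series peak, on chromosome I, ended past the entered length. Mitochondrial peaks were left out of all comparisons. Peaks were called overlapping when they shared at least 1 bp. The chance level of an overlap between lists came from 100000 random circular shifts of a list, in which all peaks of a chromosome moved together, giving a one-sided permutation p. Scores of peak groups were compared by the difference of medians with 100000 permutations of the peaks (two-sided). Shares were given with exact (Clopper-Pearson) 95% binomial intervals, densities with exact 95% Poisson intervals, and both cover counting error only. The number of peaks on X was tested against the share of X in the nuclear genome, and the number of autosomal peak midpoints on arms against 50%, with exact two-sided binomial tests. Arms were defined as the outer 25% of the length at each end of a chromosome. Clustering was tested against 1000 uniform placements of the same peak widths. These tests count peaks, which lie close to each other and are not independent replicates, so their p-values are too small. With only 2 replicates no test across samples was made, and the p-values measure the spread of peaks, not that between animals or cultures. Adjusted p-values are Benjamini-Hochberg values within each family (6 chromosomes per list, 6 arm tests, 3 differences between X and autosomal arm shares, the 2 correlations of scores at shared peaks, or 6 comparisons of score and width between X and autosomes).

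The peaks named individually were fixed by a rule before the data were examined: the 20 whole-series peaks with the highest score that a peak of both replicates overlapped, and the 5 highest-scored peaks of each replicate that no peak of the other overlapped. The tests, the other settings tried for each and a set of gene lists were fixed at the same time. Peak runs, chromosome ends, broad peaks, counts in 100 kb and 1 Mb windows, groups by score, the comparison of X and autosomal peaks in score and width, and the arm share of unshared replicate 1 peaks were examined only after the lists had been seen. Fisher's exact test of arm shares between X and autosomes was not among the tests fixed beforehand. The planned tests of gene starts and of the gene lists were not run, because the gene table at hand is on another build (WBcel235) and coordinates were not mixed between builds. No gene is therefore assigned to any peak. The overlap procedure was tested on simulated lists with the replicates' peak numbers and widths, placed uniformly within each chromosome. These lists lack the clustering of the real ones, so the procedure was not tested under clustering. With 46.7% and 89.6% of 1178 simulated peaks placed on peaks of the other list, the excess over the shifts gave 47.3% and 90.1%, and with none placed it gave 1.47%. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9.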

Results

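Peaks of a chromatin protein were mapped by ChIP-seq in adult fem-2(b245) animals in 2 ChIP replicates. The label of the experiment names KLE-2, which belongs to condensin II, a complex that compacts chromosomes, while the antibody record names the chromodomain protein CEC-1. ChIP replicate 1 had 1178 peaks over 1.89 Mb (1.89% of the nuclear genome). ChIP replicate 2 had 6421 peaks over 8.11 Mb (8.09%), 5.45 times as many peaks. The authors' list for the whole series had 9214 peaks, of which 2 lay on mitochondrial DNA and 9212 on nuclear chromosomes, where they covered 4.17 Mb (4.15%). Median peak widths were 1221 bp (interquartile range 1037 to 1754 bp) in replicate 1, 987 bp (777 to 1421 bp) in replicate 2 and 324 bp (217 to 506 bp) in the whole-series list. All positions are WS220 coordinates.

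The first comparison asked whether the replicates marked the same places. Almost all replicate 1 peaks lay on a replicate 2 peak, 1070 of 1178 (90.8%, 95% interval 89 to 92.4%), against a mean of 18.4% and a maximum of 34.6% over the circular shifts (one-sided permutation p = 1e-05, the smallest the 100000 shifts can give). In the other direction 1047 of 6421 replicate 2 peaks (16.3%, 15.4 to 17.2%) lay on a replicate 1 peak, against 3.63% by shifting (permutation p = 1e-05). The lists differ in length, and the depth behind them is unknown. When replicate 2 was limited to its 1178 highest-scored peaks, 65.1% of replicate 1 peaks (62.3 to 67.8%) were overlapped, against 5.11% by shifting, and 61.2% of those replicate 2 peaks (58.4 to 64%) lay on a replicate 1 peak.

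Replicate 2 peaks that replicate 1 also contained were the stronger and wider ones. Their median score was 3100 (interquartile range 1944 to 3100) against 323 (114 to 1058) for the 5374 peaks found in replicate 2 alone (permutation p = 1e-05), and their median width was 1738 bp against 913 bp. Their median score percentile within replicate 2 was 91.7, against 42.8 for the other peaks. A wider peak is more likely to share 1 bp with another list. The difference in width may therefore follow in part from the definition of overlap, and peaks were not matched on width. The 1070 shared replicate 1 peaks had a median score of 162 and the 108 unshared ones 72.2 (permutation p = 0.00032). Across the 1070 shared peaks, scores in the replicates were weakly related in rank (Spearman's rho = 0.33, Pearson's r = 0.22, both with adjusted permutation p = 1e-05). These are correlations across peaks, which are not independent replicates, and 68.5% of the pairs had a replicate 2 score of 3100 or more. Among the 337 pairs below that score in both replicates rho was 0.18 (permutation p = 0.00075).

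The chromosomes differed in peak density, and X had the lowest in every list. This comparison is of interest for a condensin subunit because a related condensin complex binds X in hermaphrodites for dosage compensation. In the whole-series list X had 712 peaks, or 40.2 per Mb (exact 95% interval 37.3 to 43.2), and the 5 autosomes together had 8500 peaks, or 103 per Mb. The ratio of X to autosomes was 0.39 (0.36 to 0.42, exact binomial p = 3.15e-167). It was 0.26 (0.20 to 0.33) in replicate 1, with 62 peaks on X, and 0.40 (0.36 to 0.43) in replicate 2, with 502. X held 5.26% of the replicate 1 peaks and 7.82% of the replicate 2 peaks, a difference between 2 lists of unequal length that has no replicate check, against 17.7% of the genome length. Counted in 1 Mb windows, which is less affected by clustering, the median window held 36 whole-series peaks on X (17 windows) and 95.5 on autosomes (80 windows, permutation p = 1e-05).

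**Figure D1:**
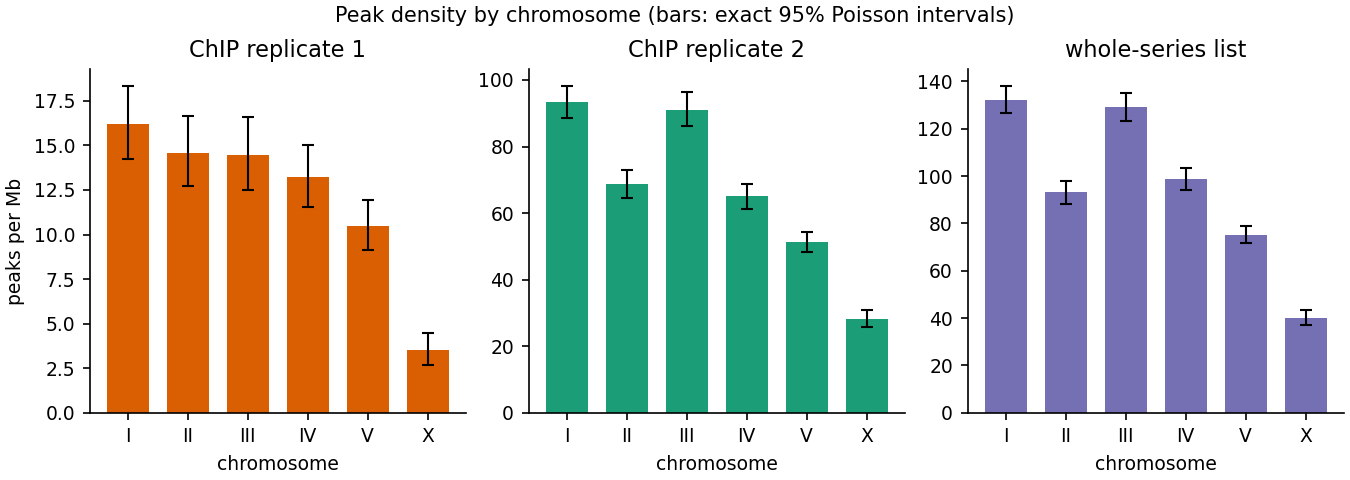
Peaks per Mb (y axis) on each nuclear chromosome (x axis) in ChIP replicate 1, ChIP replicate 2 and the whole-series list, with error bars for exact 95% Poisson intervals that cover counting error only. X is the lowest bar in each list, at 3.50, 28.3 and 40.2 peaks per Mb, and I the highest, at 16.2, 93.3 and 132 peaks per Mb.

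Chromosomes I and III were the densest autosomes in the whole-series list and in replicate 2. In the whole-series list they had 132 and 129 peaks per Mb, 1.44 and 1.41 times the genome average, and in replicate 2 they had 93.3 and 91.0 peaks per Mb (1.46 and 1.42 times the average). Adjusted exact binomial p-values were 2.45e-63 and 3.52e-49 in the whole-series list and 9.3e-48 and 2.42e-37 in replicate 2. Replicate 1 had 16.2 peaks per Mb on I (1.38 times, adjusted exact p = 5.02e-07) and 14.4 on III (1.23 times, adjusted p = 0.00343), while chromosome II was at 14.6 (1.24 times, adjusted p = 0.0013). Chromosome V lay below the average in the whole-series list (75.3 per Mb, 0.82 times, adjusted exact p = 1.56e-19) and in replicate 2 (51.2 per Mb, 0.80 times, adjusted p = 3.66e-17). In replicate 1 it was at 10.5 per Mb, 0.89 times the average, which did not pass the test (adjusted exact p = 0.0573). The genome average includes the sparse X, so each autosome stands higher against it than against the other autosomes, and these p-values partly reflect X. The autosomes together had 103 peaks per Mb in the whole-series list, 71.7 in replicate 2 and 13.5 in replicate 1. Against that density II and III were only slightly higher in replicate 1 and V was lower, which was not tested.

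The peaks on X also differed from autosomal peaks in strength and width, with values that differed between the replicates, a difference that was not itself tested. In replicate 2, peaks on X scored lower (median 234 against 492, adjusted permutation p = 0.0001) and were narrower (782 against 1020 bp, adjusted permutation p = 3e-05). Whole-series peaks on X likewise scored lower (8.16 against 10.0, adjusted permutation p = 0.0119) and were narrower (266 against 331 bp, adjusted permutation p = 3e-05). In replicate 1 the 62 peaks on X were wider than autosomal peaks (1613 against 1211 bp, adjusted permutation p = 0.00072), and their median scores of 195 against 147 did not differ significantly (adjusted permutation p = 0.0645).

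The next comparison divided chromosomes into arms and centres, which on C. elegans autosomes differ in repeat content and histone methylation. On X the same division by length was used. Peaks on X were counted more often on its arms, in tests that treat peaks as independent. Clustering was not taken into account for X, so these p-values are too small and the excess on X is less certain than they state. In the whole-series list 423 of 712 peaks on X (59.4%, 55.7 to 63.0%) were on the arms, against 50% of the length (adjusted exact binomial p = 1.73e-06), and in replicate 2 it was 286 of 502 (57.0%, 52.5 to 61.4%, adjusted p = 0.00408). In replicate 1 it was 39 of 62 (62.9%, 49.7 to 74.8%), which did not pass the test (adjusted exact p = 0.0838). The share was higher than on autosomes by 5.62 percentage points in the whole-series list (Fisher's exact test, adjusted p = 0.00635) and by 7.69 in replicate 2 (adjusted p = 0.00287). In replicate 1 the difference of 11.5 points did not pass the same exact test (adjusted p = 0.0896).

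On autosomes the arms held 4572 of 8500 whole-series peaks (53.8%, 52.7 to 54.9%, adjusted exact binomial p = 1.8e-11). With circular shifts, which keep the clustering of the peaks, the p was 0.0361. The arm share did not differ significantly from 50% in either replicate. The share was 51.4% (48.5 to 54.4%, adjusted exact p = 0.353) in replicate 1 and 49.3% (48.0 to 50.6%, adjusted p = 0.33) in replicate 2. Among the 50% of whole-series peaks with the highest scores it was 49.4% (47.9 to 50.9%, exact p = 0.464). The arm share depended on the score. In the 10% of peaks with the lowest scores 59.7% of autosomal peaks (56.3 to 63.0%) were on arms, and in the 10% with the highest scores 46.4% (43.1 to 49.8%). The share of peaks on X was 8.69% (6.95 to 10.7%) and 2.82% (1.85 to 4.10%) in the same groups.

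**Figure D2:**
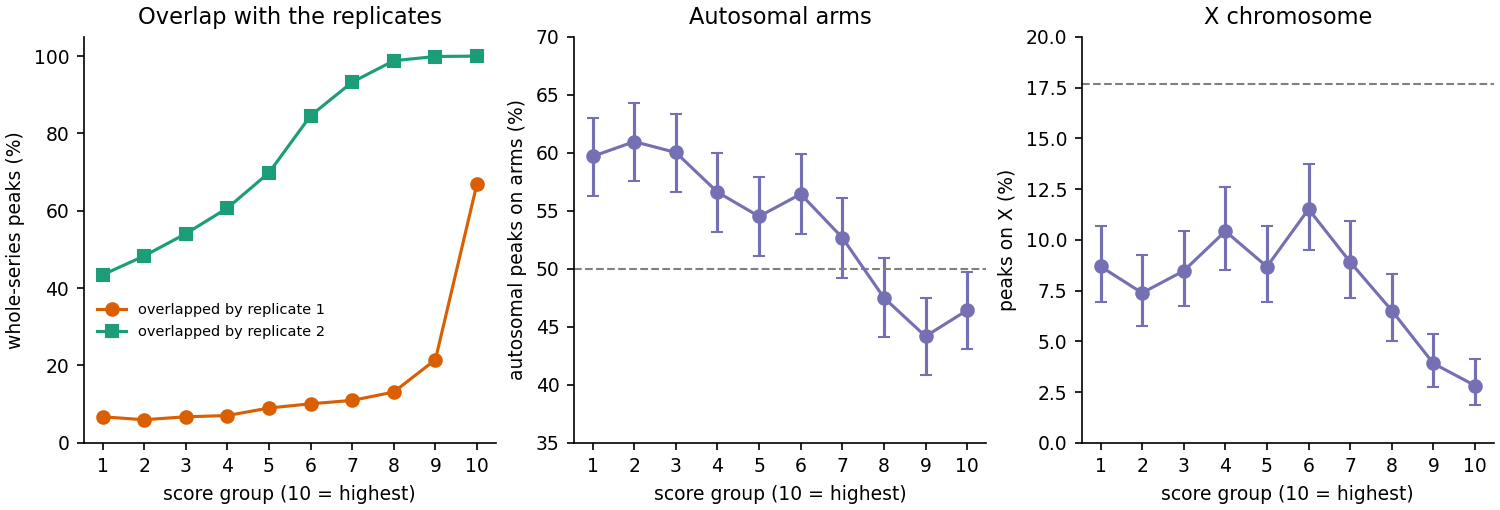
Whole-series peaks in 10 groups of equal size by score (x axis, 10 = highest): percent overlapped by a peak of each replicate (left), percent of autosomal peaks on arms (middle, dashed line at 50%) and percent on X (right, dashed line at the share of X in the genome length, 17.7%), with exact 95% binomial intervals in the middle and right panels. Overlap with replicate 2 rises from 43.4% to 100% and with replicate 1 from 6.73% to 67.0%, while the arm share is 59.7% in the lowest group and 46.4% in the highest, and the share on X is 8.69% in the lowest, 11.5% in group 6 and 2.82% in the highest.

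The whole-series list was then set against the replicates to find which of its peaks they contained. It contained 93.7% of the replicate 1 peaks (92.2 to 95%) and 85.8% of the replicate 2 peaks (85.0 to 86.7%). Of its 9212 nuclear peaks, 1321 (14.3%) were overlapped by both replicates, 5615 (61.0%) by replicate 2 alone, 137 (1.49%) by replicate 1 alone and 2139 (23.2%, 22.4 to 24.1%) by neither. Median scores in these groups were 78.8, 13.1, 7.78 and 4.64, and median widths 663, 319, 545 and 234 bp. Of the 1903 autosomal peaks in neither replicate 63.7% were on arms, compared with 62.5% of the 120 in replicate 1 alone, 51.1% of the 5225 in replicate 2 alone and 49.2% of the 1252 in both. X held 11% of the peaks in neither and 5.22% of those in both.

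Peaks lay in clusters in all 3 lists. Of the neighbouring whole-series peaks, 40.2% were separated by less than 2000 bp, against 19.3% ± 0.359 (SD over 1000 uniform placements, permutation p = 0.001, the smallest these placements can give). In replicate 2 it was 29.7% against 14.7% ± 0.385, and in replicate 1 10.8% against 2.68% ± 0.467 (permutation p = 0.001 for both). Part of the close spacing in the whole-series list lay within single replicate peaks, since 16.0% of replicate 2 peaks and 22.8% of replicate 1 peaks each overlapped at least 2 whole-series peaks. Counts per 100 kb window were related between the replicates across 1005 windows, which are not independent replicates (Spearman's rho = 0.58, Pearson's r = 0.55, permutation p = 0.0001 for both, the smallest 10000 resamples can give). The relation held within X (178 windows, rho = 0.42) and within autosomes (827 windows, rho = 0.51). The densest window of the whole-series list, chromosome I from 2000001 to 2100000, held 53 whole-series, 24 replicate 2 and 8 replicate 1 peaks.

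**Figure D3:**
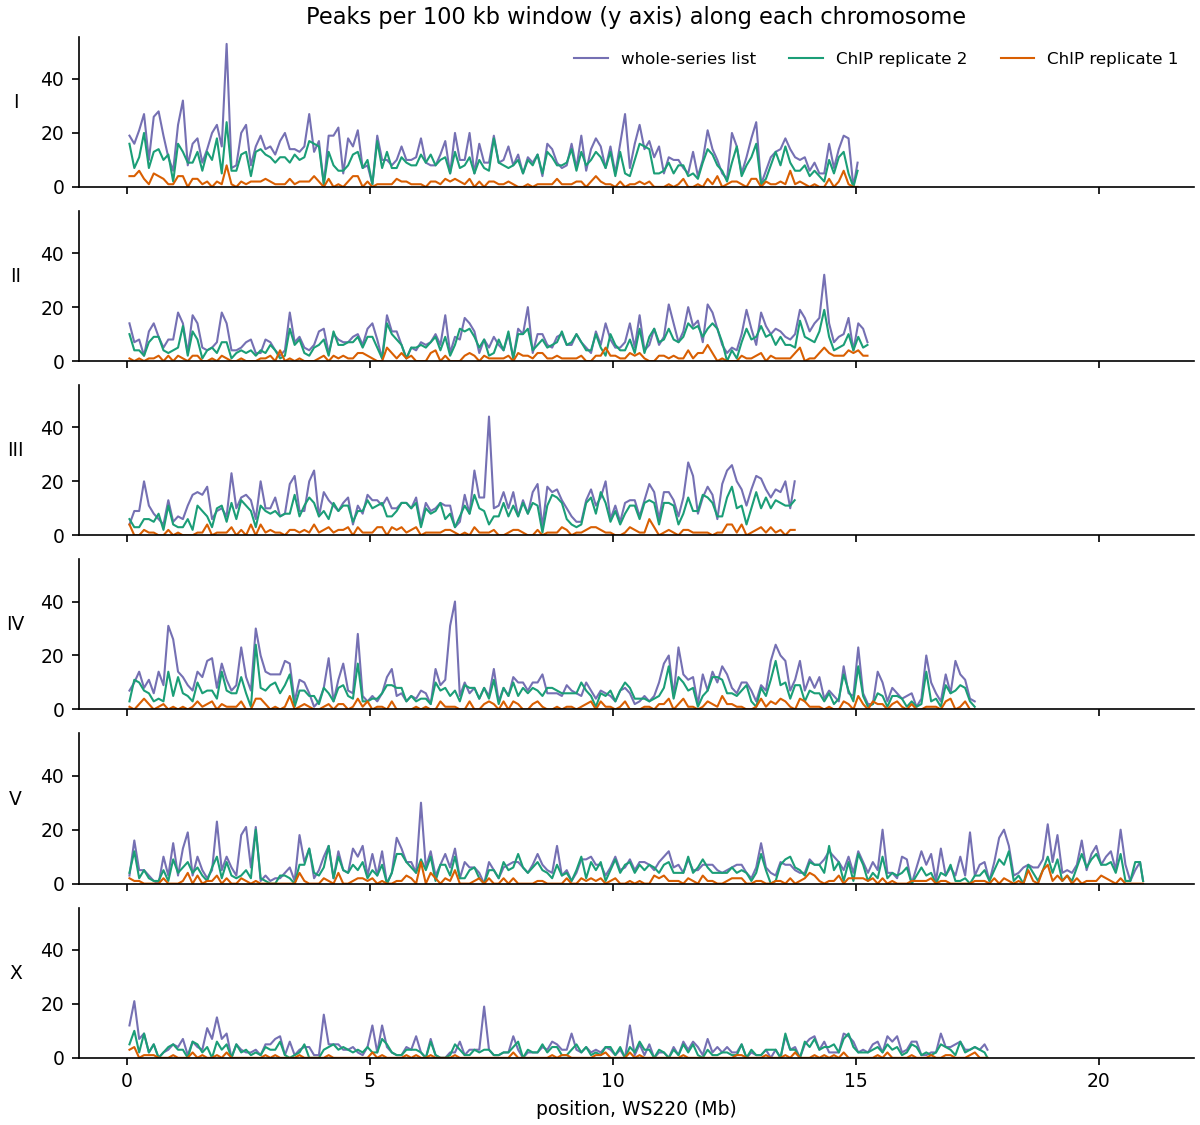
Number of peak midpoints per 100 kb window (y axis) along the 6 nuclear chromosomes (x axis, position in Mb) in the whole-series list and in both ChIP replicates. The median window of the whole-series list holds 13 peaks on I and on III and 3 peaks on X, and the window with 53 peaks on I is the highest.

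Long unbroken runs of whole-series peaks were a separate feature, described after the data were seen. Runs of at least 10 peaks with gaps under 2000 bp numbered 26 and held 403 peaks, whereas the uniform placements gave at most 1 such run. Of these 403 peaks 67.0% were in neither replicate, and 16 of the 26 runs had no replicate 2 peak, of which 10 had no replicate 1 peak either. Some runs were found in replicate 1 and not in replicate 2, such as those on chromosomes I and II. The run on I from 14885117 to 14891374 had all 10 peaks overlapped by replicate 1, which had only 1 peak in that 100 kb window. On II, from 9808067 to 9824583, replicate 1 overlapped 9 of 11. The longest extended over 34.7 kb of chromosome III, from 7405371 to 7440119, where 33 peaks with a median score of 6.57 covered 82.3% of the sequence, and 30 of them were in neither replicate. On chromosome IV, the stretch from 6708736 to 6728690 held 28 peaks and that from 890791 to 913213 held 26, all in neither replicate. In contrast, the run on chromosome III from 2099085 to 2117548 had 14 peaks, all overlapped by replicate 2 and 6 by replicate 1.

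**Figure D4:**
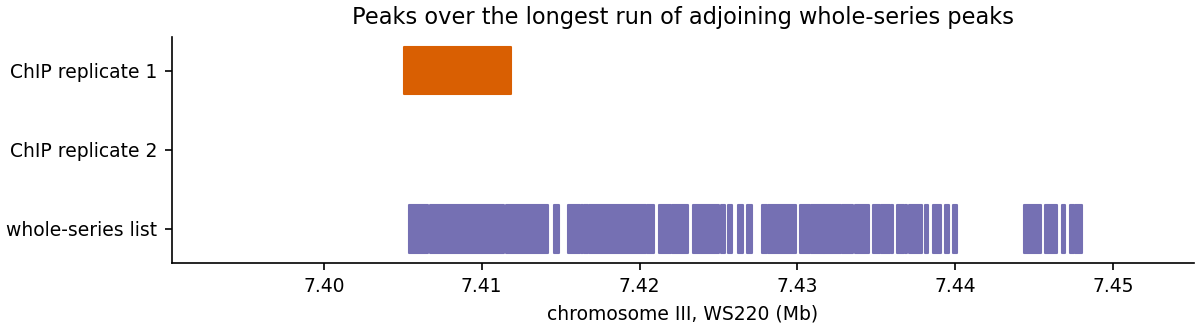
Map of peaks in each list over the longest run of whole-series peaks and its surroundings on chromosome III (x axis, position in Mb; each box is 1 peak, drawn to scale). The run from 7405371 to 7440119 holds 33 whole-series peaks, which cover 82.3% of it. It has 1 replicate 1 peak over 3 of them and no replicate 2 peak.

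Ranked by whole-series score, the strongest sites found in both replicates were spread over the autosomes. Of the 20 whole-series peaks with the highest scores among those overlapped by both replicates (scores 232.7 to 246.9), 5 lay on chromosome I, 3 on II, 4 each on III, IV and V, and none on X, and 8 lay on arms. X held only 2.82% of the 10% of whole-series peaks with the highest scores, so its absence among 20 peaks says little. By replicate score X was not absent, since 3 broad regions on X had 3100 in both replicates. In replicate 2 all 20 listed peaks had the score of 3100. In replicate 1 their scores ranged from 204 to 3100, and 13 reached 1000 or more. The highest was on chromosome I from 13609901 to 13615693 (score 246.9, with 3100 in both replicates) and was also the widest of the 20, at 5793 bp. It was followed by chromosome IV from 9196014 to 9196672 (246.31, with 2000 in replicate 1) and chromosome IV from 4388791 to 4390957 (246.06, with 1742 in replicate 1). The peak on chromosome IV from 12021952 to 12025833 (238.29) also had 3100 in both replicates. The highest on III lay from 1080392 to 1081038 (243.91, with 285 in replicate 1), on V from 10896951 to 10897696 (245.34, with 497 in replicate 1) and on II from 10033340 to 10035034 (238.13, with 2939 in replicate 1).

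Replicate 1 peaks without a replicate 2 peak had a median width of 1214 bp, against 1221 bp for those with one. The 5 of them with the highest scores were wider than that and lay on chromosome III from 2077239 to 2083031 (5793 bp, score 1476), V from 14585157 to 14591066 (5910 bp, 759), II from 1450223 to 1455100 (4878 bp, 688), V from 20433220 to 20438366 (5147 bp, 441) and X from 5047549 to 5053120 (5572 bp, 342). Their whole-series scores ranged from 8.59 to 32.1. The 5 highest-scored replicate 2 peaks with no replicate 1 peak were 946 to 2606 bp wide, with replicate 2 scores of 3197 to 3233. They lay on chromosome IV from 14956295 to 14957624 and from 16490862 to 16493467, I from 1873444 to 1874821, III from 2803817 to 2805808 and II from 11021750 to 11022695, with whole-series scores of 35.7 to 103. Of the 97 autosomal replicate 1 peaks without a replicate 2 peak, 64.9% (54.6 to 74.4%) were on arms, compared with 50.1% (47 to 53.3%) of the 1019 with one.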

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

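The settings chosen after the data were seen were local shifts of 20 to 200 kb, leaving out scores of 3100 or more, and leaving out whole-series peaks in neither replicate. Of the 40 combinations of a result and an alternative setting, 30 kept the direction and the outcome of the test. These include every alternative of the replicate overlap, of the score differences, of the correlation of scores and of the spacing, and the X to autosome ratio in all its alternatives with a test (0.26 to 0.40). The combinations are not independent checks. The overlap enters in both directions, and for X and spacing leaving out a replicate gives the other replicate's list. Among the rest, 5 changed a value that had no test. In 3 the autosomal arm share fell below 50% and in 2 it stayed above, none passing the test. The arm excess of autosomal whole-series peaks depended on which peaks were counted. It remained with arms drawn as the outer 66.7% of the length (70.7% of peaks, exact binomial p = 2.16e-15). The arm share was 53.8% with all peaks, 49.4% in the 50% of peaks with the highest scores, 49.2% in peaks found in both replicates, and 49.3% to 51.4% in the lists of single replicates. Without the peaks in neither replicate it was 50.9% (exact binomial p = 0.14). This does not place the excess in those peaks alone, since 62.5% of the autosomal peaks in replicate 1 alone were on arms. Score and runs of peaks are examined below for the peaks in neither replicate, and no biological cause was tested. With circular shifts instead of the binomial test its p was 0.0361. Counted in covered base pairs, the X to autosome ratio was 0.355 instead of 0.39, which follows from the narrower whole-series peaks on X (median 266 against 331 bp). The share of whole-series peaks in any replicate, 76.8%, was 14.3% with a reciprocal overlap of 50%, where the narrower whole-series peaks cannot cover the replicate peaks, 77.8% when all 3 lists were limited to the 50% of their peaks with the highest scores, 75.3% with replicate 2 alone and 15.8% with replicate 1 alone. The share of replicate 2 peaks in replicate 1 was 61.2% at equal list lengths. The settings for gene starts and gene lists were not run, for want of an annotation on the same build. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples have no values used here. Depth is unknown, so a peak missing from replicate 1 is not shown to be absent there.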

Other observations

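Some broad regions recurred in both replicates. Peaks of at least 5000 bp numbered 26 in replicate 1 and 45 in replicate 2, and 15 pairs of them overlapped, 3 of these on X. The widest lay on X, from 16929162 to 16939822 in replicate 1 and from 16929123 to 16940018 in replicate 2, with a score of 3100 in each. Another on X extended from 2056462 to 2064157 in replicate 1 and the third from 12662837 to 12668281, again with 3100 in each replicate. By replicate 1 width, the widest on an autosome lay on chromosome V from 7915355 to 7925477 (10123 bp in replicate 1 and 10217 bp in replicate 2). By replicate 2 width it lay on II from 14598131 to 14608916 (10786 bp, against 8554 bp in replicate 1). Of all broad peaks, 5 of 26 in replicate 1 and 3 of 45 in replicate 2 lay on X. The whole-series list also had 2 peaks on mitochondrial DNA, from 1 to 13313 (score 17.32) and from 13479 to 13796 (31.59). Its widest nuclear peak lay near the right end of chromosome I, where the ribosomal RNA genes are located, from 15060253 to 15071319 (11067 bp, score 7.74). Neither the mitochondrial peaks nor this one overlapped a replicate peak.

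The tests of X, of the runs, of both parts of the score range and of the chromosome ends were chosen only after the results they measure, or values that largely fix them, had been seen. The match on score in 10 bins was stated before.

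The low density on X was not confined to parts of the chromosome. In the inner 50% of the chromosomes the X to autosome ratio was 0.343 (0.303 to 0.386), a value that follows from the arm shares already given and is no independent test, but that a loss on the arms of X alone would not leave. In addition, 100% of the 17 windows of 1 Mb on X lay below the autosomal median, which argues against a few empty stretches. A weaker signal over all of X, which leaves its peaks below the score threshold, may contribute. In replicate 2 the share of X was 10.0% in the 20% of peaks with the lowest scores and 3.12% in the 20% with the highest (Fisher's exact test, p = 7.77e-13). In the whole-series list it was 8.03% and 3.37% (Fisher's exact test, p = 9.31e-10). These lists are not separate observations, since 75.3% of whole-series peaks lay on a replicate 2 peak and 15.8% on a replicate 1 peak. In replicate 1 the shares ran the other way, 4.26% in the lowest and 8.94% in the highest (Fisher's exact test, p = 0.0616). This leaves the weaker signal over all of X under the score threshold open. No biological explanation was tested, because the design has a single condition.

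Whole-series peaks in neither replicate lay on autosomal arms more often than those in replicate 2. If weak peaks lay on arms whichever list held them, the difference would vanish at equal score. Matched on score in 10 bins it was 10.4 percentage points (permutation p = 0.0001, the smallest 10000 resamples can give), but the highest bin spanned scores of 9.08 to 65.3, and from 6 to 7.02 the shares were 54.3% in neither and 55.7% in replicate 2, from 7.03 to 9.06 they were 55% and 53%. With finer bins the difference was 13 points up to a score of 4.61 (permutation p = 0.0001) and 5.03 points above it (permutation p = 0.0092). At low scores the difference thus remained in these peaks. The permutations treat peaks as independent although they cluster, so these p-values are too small. For all autosomal whole-series peaks, circular shifts that keep the clustering gave the arm share an SD of 1.85 points. The match therefore cannot decide against the explanation, which stays open in both parts. Leaving out the runs of weak peaks did not lower the arm share, so they do not account for the excess. It was 63.7% with them and 67.4% without (65.1 to 69.6%, an interval that covers counting error only). No biological explanation was tested, because the design has a single condition.

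All 6 left chromosome ends had a peak within 2000 bp in both replicates, with scores of 590 to 1419 in replicate 1 and 179 to 2512 in replicate 2, while chance would give 4.24% and 20.9% of ends. None of the right ends (0 of 6) had a peak in both replicates, with 1 in replicate 1 and 0 in replicate 2 (Fisher's exact test against the left ends, p = 0.0152 and p = 0.00216). The whole-series list had a peak at 4 left and 3 right ends (Fisher's exact test, p = 1), with right-end scores of 6.73 to 27.4, so signal at both ends of the chromosomes alike stays open. A caller effect at the first base in the replicate lists remains a candidate explanation, since the whole-series list overlapped 4 of the 6 left end peaks of replicate 1, which neither excludes nor requires it. The whole-series scores there were 11.6 on I, 22.9 on II, 22.6 on V and 2.3 on X, against a list median of 9.81. No biological explanation was tested for this pattern.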
